A study of Mus musculus with 19 samples.

How the data were processed

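Gene expression was measured in single nuclei of the mouse striatum, sorted by FACS with 7-AAD, with 10x Genomics 3' v3.1 libraries sequenced on a NextSeq 2000. Per the submitters' processing notes, Cell Ranger 7.1.0 and mm10 were used, and neither the counting of intronic reads nor the annotation release was stated. The authors deposited raw UMI counts, 1 matrix of genes by called barcodes per library, with 32285 genes. Matrices were present for 17 of 19 libraries, and MitoPark 15-week replicates 2 and 3, which had none, were not analysed here. All values were checked to be whole counts, and no pair of libraries had the same matrix. Spatial data named in the study's description were not part of the files. Gene coordinates came from the GENCODE M21 annotation of mm10, which matched 32158 of the identifiers.

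The labels number the controls in 2 ways that differ for 3 of them, and the numbers in the titles are used here. The labels do not give the hemisphere, the age of the controls or the sequencing runs. Whether replicate numbers pair animals between groups stayed open. When libraries were correlated, replicate 2 matched its own number best in each class checked and replicate 1 in none, with replicate 3 mixed. Shared symbols (38) were summed.

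Of 118582 barcodes, the 114426 with at least 500 genes and under 5% mitochondrial counts were kept. Doublets were scored per library against 2 simulated doublets per nucleus, and nuclei with a score over 0.2, or in 1 of 22 clusters with over 25% such nuclei, were dropped (8458, 7.39%). Counts were scaled to the same total and log-transformed, and the 3000 most variable genes, 50 principal components and 20 nearest neighbours were used for Leiden clustering at a resolution of 1.5, with no integration of libraries. Clusters were named by marker lists written before the data were examined, from the mean standardized level of a list (at least 1.3 and 0.3 above the next list, with 3 markers over 20 CPM). Nuclei got the same class when each library was clustered on its own in 62.77% of cases for D1 SPN-like, 85.86% for D2 SPN-like, 98.38% for astrocyte-like, 92.03% for microglia-like and 98.73% for oligodendrocyte-like nuclei. When no gene called in any comparison was used for clustering, these shares lay between 99.38% and 99.98%.

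Raw counts were summed per library and class (at least 20 nuclei), so the library of 1 animal was the replicate. The sums held 1574339 to 10117890 UMIs in D1 SPN-like, 1015077 to 8228044 in D2 SPN-like, 113542 to 1408844 in astrocyte-like, 1234626 to 11266660 in oligodendrocyte-like and 118826 to 1653302 in microglia-like nuclei, and the biological coefficients of variation of the fits were 11.9%, 12.9%, 14.9%, 16% and 15.1%. One edgeR 4.0.16 quasi-likelihood model per class (TMM, filterByExpr, glmQLFit with robust = TRUE) held 5 groups, C57BL/6J, 6-OHDA, floxed, MitoPark 11 weeks and MitoPark 15 to 18 weeks. The comparisons were 6-OHDA against C57BL/6J, each MitoPark group against floxed, late against 11-week MitoPark, and floxed against C57BL/6J. A Benjamini-Hochberg adjusted p under 0.05 counted as a change. The difference between D1 and D2 SPN-like nuclei was an interaction term with the animal as a block, and the difference between models was the contrast of both effects.

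For 27 gene lists, limma 3.58.1 camera was used with a preset inter-gene correlation of 0.01 on lists with at least 5 tested members, and an estimated correlation and fry were alternatives. Adjusted p for lists were taken over the lists of a class and comparison. Class shares were compared by two-sided exact permutation tests with Benjamini-Hochberg adjustment. Gene lists, markers, tests and most alternatives were chosen before the data were examined. Genes named in the text were chosen by rule, and some that the rule chose are not reported here. For SPNs these were up to 5 with the largest change in each direction among those that changed, with a mean log2 CPM of at least 4 and every model library on the same side of the control mean. The number per direction was 2 for astrocytes, oligodendrocytes and microglia and 1 for smaller classes. The rule added up to 4 changed members of each list with the smallest p, and Drd1, Drd2, Adora2a, Penk, Tac1, Pdyn, Ppp1r1b, Tfam, Gfap, P2ry12, Apoe, C4b and Mbp in set classes.

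The alternatives were DESeq2 1.42.0 with its own size factors, RLE factors in place of TMM, no filter beyond 1 count, only the libraries of the groups compared, all 7 controls as 1 group, doublets kept, stricter nuclei (at least 1000 genes, under 1% mitochondrial counts), each library clustered on its own, log2 median UMIs per nucleus (depth) or log2 CPM of Xist as a covariate, each library left out in turn, the 15-week or 18-week libraries alone, and replicate numbers as a block. Floxed in place of C57BL/6J controls, and either pair of floxed controls left out, were added after the data had been seen, as was a fit with each floxed pair as its own group. A fit in which a group has 1 library takes the spread from the other groups. Other splits of the libraries were refitted in the same way.

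The pipeline was tested on simulated data with 200 changed genes. In the 6-OHDA comparison of D1 SPN-like nuclei it found 44.8%, 88.1% and 98.5% of 1.5-fold, 2-fold and 4-fold changes with 4 false calls, and in astrocyte-like nuclei 7.5%, 22.4% and 86.4% with 2. Smaller changes in astrocyte-like nuclei, and in microglia-like nuclei (43.3% of 2-fold changes found), therefore stay open. R 4.3.3 and Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and python-igraph 0.11.9 were used.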

Results

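Nuclei of the striatum were profiled by single-nucleus RNA sequencing in 2 mouse models of dopamine loss and in their controls. In the toxin model, 6-hydroxydopamine (6-OHDA), a neurotoxin taken up by catecholamine neurons, was injected at 0.6 µg/µL on 1 side into the medial forebrain bundle, the tract that carries dopamine axons to the striatum. In the genetic model, MitoPark, Cre recombinase driven by the dopamine transporter gene Slc6a3 removes Tfam, a mitochondrial transcription factor, from dopamine neurons. Count matrices were present for 3 mildly lesioned mice and 3 untreated C57BL/6J controls, and for 3 MitoPark mice of 11 weeks, 2 of 15 weeks, 2 of 18 weeks and 4 controls with the floxed Tfam allele. The MitoPark mice of 15 and 18 weeks were pooled as the late group (n = 4). Each library came from the striatum of 1 hemisphere of 1 brain, so p-values measure the spread between libraries of single animals. The controls of the toxin model had no sham injection, so the toxin and the surgery were not separated.

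The C57BL/6J libraries 1 to 3 held 38172767, 75533510 and 14446047 UMIs, and the 6-OHDA libraries 1 to 3 held 43138442, 89623109 and 34848514. The floxed control libraries 4, 5, 6 and 7 held 29052451, 41319440, 38593850 and 44508380 UMIs. MitoPark libraries of 11 weeks held 46751242, 55291974 and 19841832 UMIs, those of 15 weeks (replicates 1 and 4) 68248441 and 69726576, and those of 18 weeks 67064725 and 38404839. Medians per barcode ran from 2348 to 7261.5 UMIs. After filtering, 105968 nuclei were grouped into 80 clusters, and clusters were named by marker genes as "like" a known class. The spiny projection neurons (SPNs), the output neurons of the striatum, gave 7254 D1 SPN-like and 6555 D2 SPN-like nuclei. Glia gave 39635 oligodendrocyte-like, 9586 microglia-like, 3139 astrocyte-like and 2700 oligodendrocyte precursor-like nuclei. A further 17.69% of nuclei lay in 23 clusters that no marker list named. Changes below are log2 fold changes ± SE of the edgeR fit, and levels are mean CPM, counts scaled to the size of the library, ± SD over libraries.

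The 4 floxed controls fell into 2 pairs by the library names in the labels, replicates 4 and 6 and replicates 5 and 7. Between these pairs 336 genes differed in D1 SPN-like nuclei and 283 in D2 SPN-like nuclei, against 6 in astrocyte-like, 2 in oligodendrocyte-like and 1 in microglia-like nuclei. The MitoPark gene counts of these 5 classes are therefore also given against each pair. The pairs were taken from the labels after the data had been seen.

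The share of nuclei in each class was compared between models and controls. D1 SPN-like nuclei made up 7.18% ± 1.16 of all nuclei after 6-OHDA and 4.63% ± 1.20 in controls (SD, n = 3 each, two-sided exact permutation p = 0.10, the smallest that 3 against 3 libraries allow). Astrocyte-like nuclei made up 3.12% ± 0.34 in 11-week MitoPark mice and 4.68% ± 0.86 in floxed controls (SD, n = 3 and 4, exact permutation p = 0.0571, again the smallest possible). Newly formed oligodendrocyte-like nuclei were 0.221% ± 0.038 in late MitoPark mice and 0.383% ± 0.075 in floxed controls (SD, n = 4 each, exact permutation p = 0.0286, adjusted p = 0.543). No class passed the exact permutation test after adjustment in any of the 3 comparisons.

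**Figure D1:**
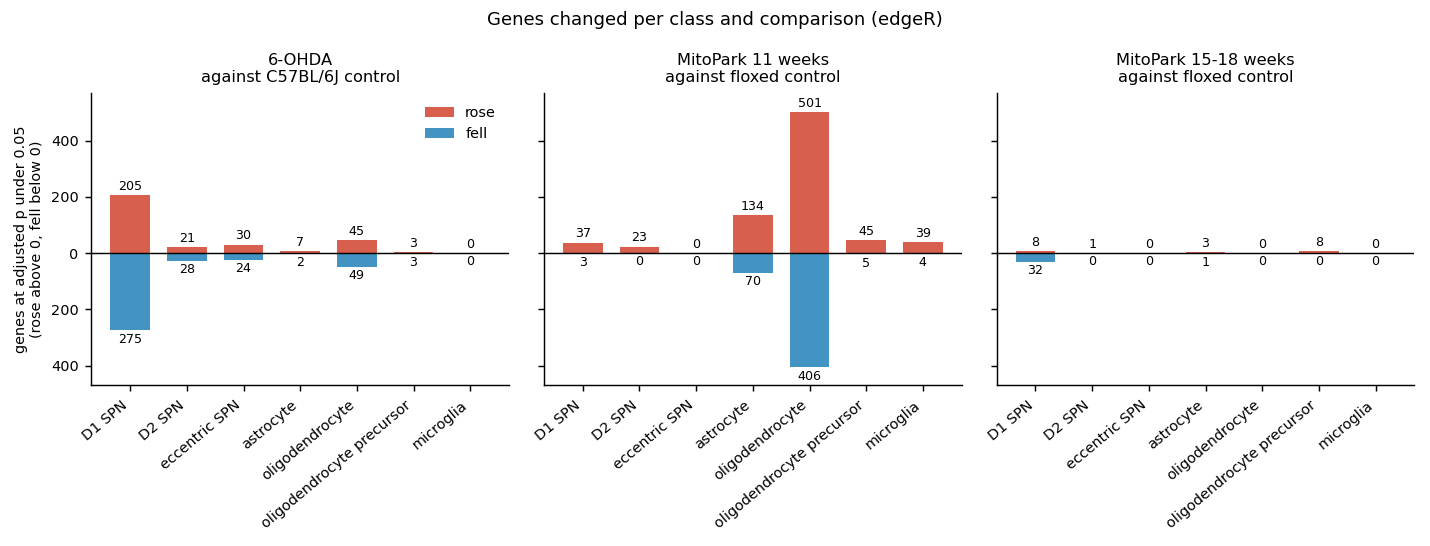
Number of genes that rose (bars above 0) and fell (bars below 0) in each class of nuclei, for 6-OHDA against C57BL/6J controls, 11-week MitoPark against floxed controls and late MitoPark against floxed controls, at an edgeR adjusted p under 0.05. The tallest bars are those of oligodendrocyte-like nuclei at 11 weeks (501 rose, 406 fell) and of D1 SPN-like nuclei after 6-OHDA (205 rose, 275 fell).

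The mild 6-OHDA lesion was compared with untreated C57BL/6J mice to ask how striatal cells respond to partial loss of dopamine. In D1 SPN-like nuclei, which carry the excitatory D1 dopamine receptor, 10 of 29 genes induced by neuronal activity fell, and single genes of calcium release, synapses and axon guidance changed too. The immediate early gene Nr4a1 fell from 30.4 ± 9.59 to 3.71 ± 0.95 CPM (-3.06 ± 0.59), Fos by 4.35 ± 0.87 on the log2 scale, the secreted peptide precursor Vgf by 2.17 ± 0.38 and the postsynaptic scaffold gene Homer1 by 0.76 ± 0.14 (n = 3 and 3). The ryanodine receptor Ryr1, a channel that releases calcium from internal stores, fell from 92.6 ± 3.04 to 19.0 ± 0.59 CPM (-2.29 ± 0.18, adjusted p = 1.01e-06). The orphan receptor gene Gpr149 rose from 36.1 ± 10.9 to 96.7 ± 16.8 CPM (1.46 ± 0.19, adjusted p = 0.000242), and the synaptic vesicle gene Sv2c from 246 ± 18.0 to 416 ± 26.5 CPM (0.77 ± 0.097). In all, 480 of 12983 tested genes changed (205 rose, 275 fell), with 2104 at an unadjusted p under 0.05 and 529 by DESeq2.

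Of 29 activity-regulated genes tested in D1 SPN-like nuclei, 10 fell, 0 rose and 19 did not pass, and 20 fell when adjusted over the list alone. The list's median was -1.44 and its camera adjusted p was 5.27e-15, with an adjusted p of 0.404 with an estimated correlation and 0.0422 by fry, which tests whether a set's genes move on balance 1 way. The same list was lower in floxed than in C57BL/6J controls, in D1 (camera adjusted p = 0.00856, adjusted p = 0.883 with an estimated correlation) and in D2 SPN-like nuclei (0.00146 and 0.80). Of 39 axon guidance and ephrin genes, 2 rose and 6 fell (adjusted over the list alone 2 and 9, camera adjusted p = 0.00397, adjusted p = 0.646 with an estimated correlation). Among them the guidance ligand Slit1 rose by 1.73 ± 0.25, while Ntng1 (-1.63 ± 0.23), Sema6d (-0.63 ± 0.10) and the ephrin receptor Epha3 (-0.60 ± 0.11) fell. Calcium and sodium channels were lower as a list (camera adjusted p = 0.0327, adjusted p = 0.706 with an estimated correlation), with Ryr1 the 1 gene of 30 that fell and 3 when adjusted over the list alone. Genes of the disease-associated microglia list were higher (2 of 16 rose, 3 adjusted over the list alone, camera adjusted p = 0.00397, adjusted p = 0.597 with an estimated correlation), through the lipase Lpl (0.73 ± 0.17) and the cathepsin Ctsb (0.56 ± 0.14), both also expressed outside microglia. Cytosolic ribosomal protein genes, read here as a sign of RNA content, were higher as a list with no member passing (median 0.34, camera adjusted p = 4.01e-05, adjusted p = 0.706 with an estimated correlation).

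Other synaptic genes in D1 SPN-like nuclei moved without a call for their list. The kainate receptor auxiliary subunit Neto2 fell from 314 ± 33.5 to 174 ± 12.2 CPM (-0.85 ± 0.099, adjusted p = 1.79e-05). The vesicle priming gene Unc13a (-0.82 ± 0.14), the adhesion gene Nrxn3 (-0.44 ± 0.090), the GABA receptor subunit Gabra5 (-0.77 ± 0.16) and the scaffold gene Dlgap3 (-0.48 ± 0.11) fell. Among potassium channels, Kcnn2 (-0.76 ± 0.14) and Kcnq3 (-0.44 ± 0.090) fell and Kcnj3 rose (0.93 ± 0.19). The clock gene Per3 (1.11 ± 0.19), the histamine receptor Hrh3 (1.10 ± 0.22), the fatty acid hydroxylase Fa2h (1.49 ± 0.30) and the cholesterol transporter Abca1 (1.49 ± 0.27) rose, and Srebf2 (-0.56 ± 0.13) of cholesterol synthesis fell. Pde1b, a phosphodiesterase of dopamine signalling, fell by 0.50 ± 0.091 on the log2 scale. The dopamine receptor Drd1 (0.09 ± 0.12, adjusted p = 0.77), the peptide precursors Tac1 (-0.32 ± 0.18, adjusted p = 0.408) and Pdyn (-0.52 ± 0.21, adjusted p = 0.194) and Ppp1r1b (0.28 ± 0.13, adjusted p = 0.305) did not pass.

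On mm10, Gpr149 spans chromosome 3, 62529077 to 62605140, Ryr1 chromosome 7, 29003344 to 29125179, Homer1 chromosome 13, 93299635 to 93405129, Neto2 chromosome 8, 85636588 to 85700924, and Sv2c chromosome 13, 95954594 to 96132577. The D1 count fell to 299 and 304 without C57BL/6J replicate 1 or 2, and to 311, 227 and 298 without 6-OHDA replicate 1, 2 or 3. It was 814 with no filter on low counts, 880 against all 7 controls and 1038 with the floxed controls in place of C57BL/6J. In each of the 6 fits with 1 library left out, 22 of the 46 genes chosen by rule that passed still passed, Ryr1, Gpr149, Neto2, Sv2c, Slit1, Homer1, Unc13a and Vgf among them. Nr4a1 and Fos were not among the 22.

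**Figure D2:**
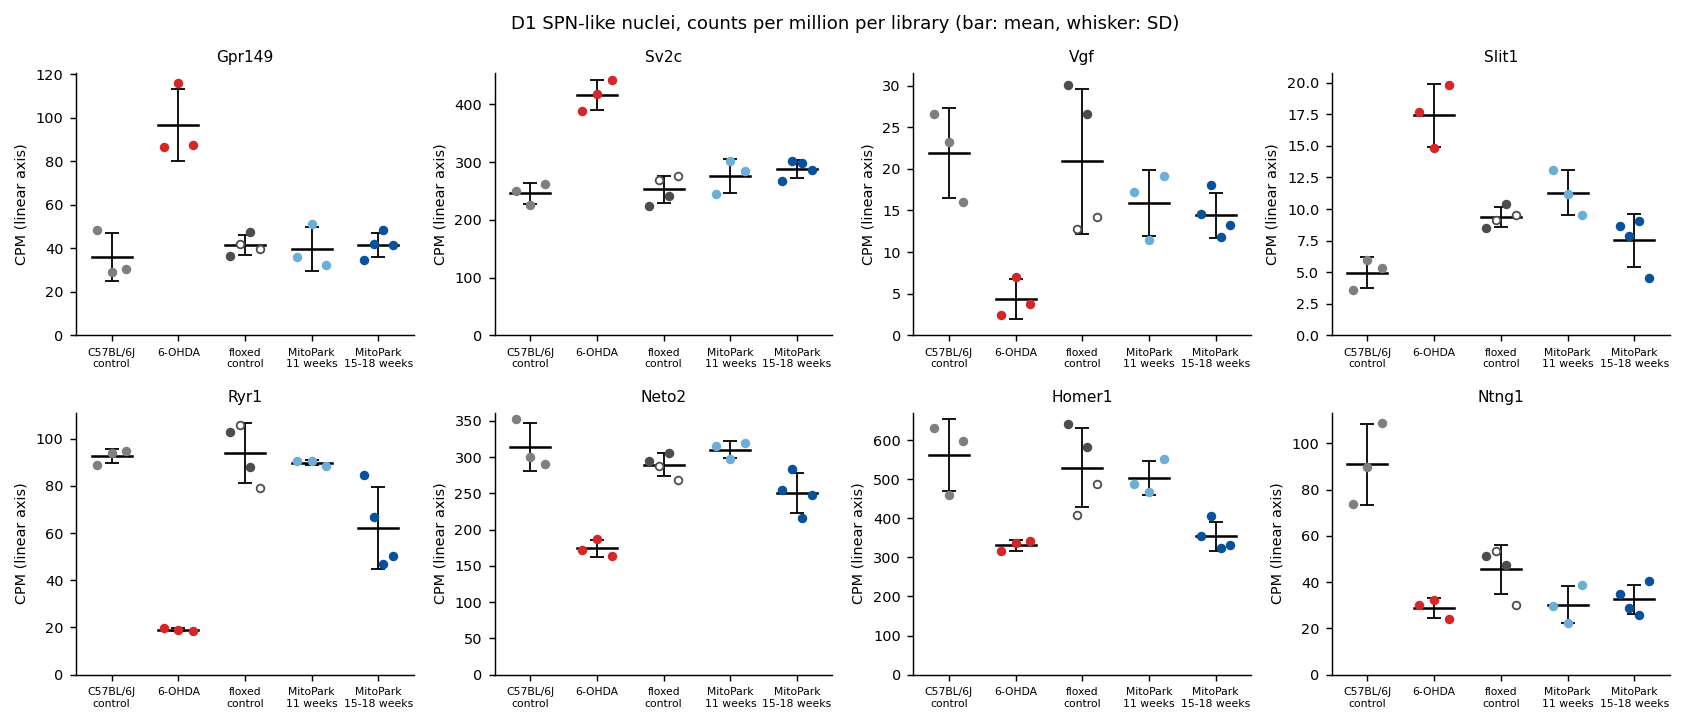
Expression of 8 genes in D1 SPN-like nuclei (CPM) in C57BL/6J controls, 6-OHDA, floxed controls, 11-week MitoPark and late MitoPark. Points are libraries, with open points for floxed controls 5 and 7, bars are group means and whiskers SD; Ryr1 lies at 19.0 ± 0.59 CPM after 6-OHDA and at 92.6 ± 3.04 CPM in the C57BL/6J controls.

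D2 SPN-like nuclei, which carry the inhibitory D2 receptor, were compared in the same way. Both GABA-synthesizing enzymes rose, Gad1 from 131 ± 3.07 to 192 ± 11.0 CPM (0.55 ± 0.10, adjusted p = 0.0121) and Gad2 by 0.55 ± 0.12 on the log2 scale. The long noncoding RNA Mir670hg rose from 56.4 ± 20.1 to 309 ± 42.0 CPM (2.36 ± 0.39), and the potassium channel Kcnn2 rose (0.57 ± 0.12). The adhesion gene Igsf21 fell from 36.6 ± 10.9 to 12.5 ± 0.46 CPM (-1.62 ± 0.26), and Lyn (-1.25 ± 0.23) and Neto2 (-0.62 ± 0.11) fell too. Of 39 axon guidance genes Efnb3, Sema6d, Epha3 and Robo1 fell, by 0.77 ± 0.16, 0.79 ± 0.15, 0.68 ± 0.15 and 0.38 ± 0.084, with no call for the list. Penk, the enkephalin precursor, was at 530 ± 112 against 365 ± 80.8 CPM (0.53 ± 0.20, adjusted p = 0.328), and Drd2 (0.02 ± 0.097, adjusted p = 0.992) and Adora2a (-0.18 ± 0.11, adjusted p = 0.609) did not pass.

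In D2 SPN-like nuclei 49 of 12635 genes changed (21 rose, 28 fell), with 1332 at an unadjusted p under 0.05 and 101 by DESeq2, and 0 of the lists were called by camera, against 5 in D1. The count was 6 and 22 without C57BL/6J replicate 1 or 2 and 1 and 5 without 6-OHDA replicate 2 or 3, and no named gene passed in all 6 such fits. It was 358 with no filter, 89 with only these 2 groups fitted, 325 against all 7 controls, 503 with the floxed controls in place of C57BL/6J and 88 with replicate numbers as a block.

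The difference between the classes was tested directly, with both classes of each animal paired. The 6-OHDA change differed between D2 and D1 SPN-like nuclei in 798 genes, higher in D2 for 555 and lower for 243. Nr4a1 differed by 3.70 ± 0.22, Fos by 3.59, Vgf by 3.03, Ryr1 by 2.11 ± 0.15 (adjusted p = 1.3e-12), Kcnn2 by 1.35 ± 0.10 and Homer1 by 0.77 on the log2 scale, all lower in D1. Slit1 (-1.74), Hrh3 (-1.52), Gpr149 (-1.32), Abca1 (-1.24), Per3 (-0.91) and Sv2c (-0.38, adjusted p = 0.0036) rose more in D1. Nrxn3 (adjusted p = 0.0503) did not pass. The count fell to 480 without C57BL/6J replicate 2 and to 460 without 6-OHDA replicate 2.

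Among glia after 6-OHDA the highest count of changed genes was in oligodendrocyte-like nuclei. The complement gene C4b rose from 5.99 ± 1.33 to 33.3 ± 10.5 CPM (2.53 ± 0.27, adjusted p = 0.000247), the lipid carrier Apoe from 190 ± 14.8 to 585 ± 197 CPM (1.62 ± 0.22), and the class I genes H2-D1 (1.82 ± 0.32) and H2-K1 (1.44 ± 0.31) rose too. The decarboxylase Ddc rose from 26.6 ± 2.60 to 78.0 ± 6.30 CPM (1.57 ± 0.20), the GABA receptor subunit Gabrr2 by 1.88 ± 0.22, and the lipid regulator Srebf1 by 0.77 ± 0.17. Synaptic adhesion and guidance genes Nlgn1 (-0.57 ± 0.084) and Dcc (-0.97 ± 0.18) and Efr3b (-1.11 ± 0.17) fell. Mbp (-0.06 ± 0.12, adjusted p = 0.951) did not pass. C4b spans chromosome 17, 34728380 to 34743882, and Apoe chromosome 7, 19696109 to 19699188.

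Of 23 disease-associated oligodendrocyte genes 4 rose, 0 fell and 19 did not pass (6 rose when adjusted over the list alone, median 1.00, camera adjusted p = 3.88e-08, adjusted p = 0.245 with an estimated correlation). Of 7 reactive astrocyte genes measured in oligodendrocyte-like nuclei 3 rose (C4b, H2-D1, H2-K1, adjusted over the list alone 4, camera adjusted p = 2.37e-06, adjusted p = 0.128 with an estimated correlation). Glucocorticoid-responsive genes were higher with 0 of 21 passing (3 adjusted over the list alone, median 0.93, camera adjusted p = 2.35e-06, adjusted p = 0.67 with an estimated correlation). In this class cluster 0 held 55.6% ± 11.1 of the nuclei after 6-OHDA and 32.4% ± 15.4 in controls, and cluster 1 held 13.7% ± 7.35 against 35.2% ± 15.7 (SD, n = 3 each). In all 94 of 13327 genes changed (45 rose, 49 fell), with 1508 at an unadjusted p under 0.05 and 233 by DESeq2. The count was 40, 34 and 57 without C57BL/6J replicate 1, 2 or 3, 33 and 25 without 6-OHDA replicate 2 or 3, 15 with only these 2 groups fitted, 413 against all 7 controls, 55 with each library clustered on its own, 28 with depth as a covariate and 24 with replicate numbers as a block. C4b, Apoe, Ddc, Gabrr2, Nlgn1 and Efr3b passed in all 6 fits with 1 library left out.

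Astrocyte-like nuclei changed in 9 of 8865 genes after 6-OHDA (7 rose, 2 fell, 683 at an unadjusted p under 0.05, 27 by DESeq2). Fkbp5, a glucocorticoid-induced chaperone, rose from 8.59 ± 7.54 to 67.8 ± 27.5 CPM (2.48 ± 0.47), Rbms3 fell (-1.08 ± 0.20), and Gfap, a marker of reactive astrocytes, did not pass (-0.31 ± 0.46, adjusted p = 0.944). Cholesterol synthesis genes were lower as a list with 0 of 24 passing (1 adjusted over the list alone, camera adjusted p = 1.59e-05, adjusted p = 0.586 with an estimated correlation). The count was 3 and 1 without C57BL/6J replicate 1 or 2, 3 without 6-OHDA replicate 2 or 3, 1 with doublets kept, 40 with no filter and 61 against all 7 controls. Microglia-like nuclei changed in 0 of 10140 genes by edgeR (546 at an unadjusted p under 0.05, 3 by DESeq2, 2 without C57BL/6J replicate 1, 15 against all 7 controls and 50 with no filter). There P2ry12, a marker of resting microglia, did not pass (0.04 ± 0.14), and Apoe stood at 427 ± 318 against 130 ± 7.84 CPM (1.74 ± 0.56, adjusted p = 0.682). Interferon and antigen presentation genes of microglia-like nuclei were higher as a list with 0 of 25 passing, also adjusted over the list alone (camera adjusted p = 0.0054, adjusted p = 0.427 with an estimated correlation).

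Eccentric SPN-like nuclei, a rarer SPN type, changed in 54 of 9356 genes after 6-OHDA (30 rose, 24 fell, 944 at an unadjusted p under 0.05, 70 by DESeq2). Vgf fell from 54.1 ± 9.98 to 13.9 ± 0.92 CPM (-1.92 ± 0.27, adjusted p = 0.000196), Ryr1 by 0.97 ± 0.21 and Unc13a by 0.77 ± 0.16 on the log2 scale. Pdzrn4 (1.97 ± 0.30), Per3 (0.87 ± 0.18) and the glutamate receptor Gria4 (0.75 ± 0.14) rose. Cluster 61 held 16.3% ± 15.3 of this class in controls and 0.81% ± 0.87 after 6-OHDA (SD, n = 3 each).

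MitoPark mice of 11 weeks were compared with floxed controls of unstated age, so model and age were not separated. In glia, genes that respond to glucocorticoid hormones rose. Fkbp5 rose from 2.83 ± 1.00 to 91.4 ± 20.4 CPM in astrocyte-like nuclei (4.99 ± 0.46, adjusted p = 3.39e-08) and from 16.3 ± 13.7 to 247 ± 58.9 CPM in oligodendrocyte-like nuclei (4.22 ± 0.85), n = 3 and 4. In oligodendrocyte-like nuclei the lipid droplet gene Plin4 (4.81 ± 0.70), the kinase gene Sgk1 (3.86 ± 0.87), Pdk4 (2.57 ± 0.44) and the cell cycle inhibitor Cdkn1a (4.40 ± 0.81) rose. In microglia-like nuclei Tsc22d3, a glucocorticoid-induced leucine zipper gene, rose from 22.4 ± 18.8 to 140 ± 53 CPM (3.03 ± 0.58), with Zbtb16 (4.14 ± 0.73) and Sult1a1 (2.06 ± 0.44). Fkbp5 lies on chromosome 17, 28399094 to 28517527, and Sgk1 on chromosome 10, 21882184 to 21999903.

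Of 21 glucocorticoid-responsive genes in oligodendrocyte-like nuclei 15 rose and 0 fell (adjusted over the list alone 17 and 0, median 1.98, camera adjusted p = 1.19e-17, adjusted p = 0.238 with an estimated correlation). In astrocyte-like nuclei 7 of 16 rose (10 up and 1 down adjusted over the list alone, camera adjusted p = 7.91e-12, adjusted p = 0.129 with an estimated correlation), and in microglia-like nuclei 4 of 13 (9 adjusted over the list alone, camera adjusted p = 9.25e-14, adjusted p = 0.0672 with an estimated correlation). In oligodendrocyte precursor-like nuclei 3 of 10 rose (6 adjusted over the list alone), Fkbp5 (2.54 ± 0.37), Klf9 (1.90 ± 0.28) and Htra1 (2.14 ± 0.39), with a camera adjusted p of 9.89e-18. This was the only list call of 215, among 879 tests over classes and 5 comparisons, that held with an estimated correlation (adjusted p = 0.00795). The list was also called against each floxed pair in astrocyte-like, oligodendrocyte-like and microglia-like nuclei, with adjusted p of 1.42e-08, 9.24e-11 and 0.000132 against controls 4 and 6. Against controls 4 and 6 alone Fkbp5 passed in astrocyte-like nuclei (5.03, adjusted p = 0.000112), while Fkbp5 (3.22, adjusted p = 0.131), Plin4 (4.41, adjusted p = 0.0546) and Sgk1 (3.23, adjusted p = 0.185) of oligodendrocyte-like nuclei did not, nor did Tsc22d3, Zbtb16 and Sult1a1 of microglia-like nuclei.

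**Figure D3:**
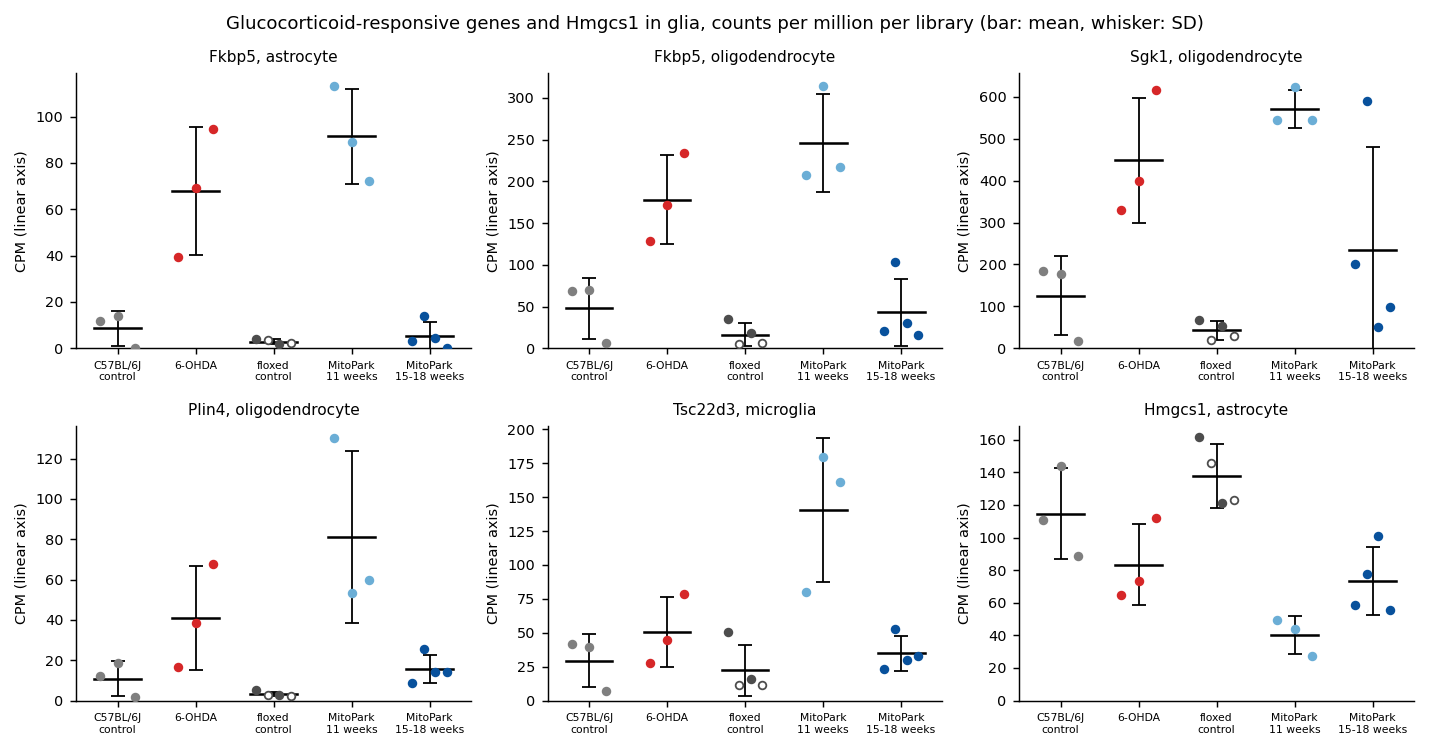
Expression (CPM) of Fkbp5, Sgk1, Plin4, Tsc22d3 and Hmgcs1 in the glial class named over each panel, in C57BL/6J controls, 6-OHDA, floxed controls, 11-week MitoPark and late MitoPark. Points are libraries (open for floxed controls 5 and 7), bars are means and whiskers SD; Fkbp5 in astrocyte-like nuclei lies at 91.4 ± 20.4 CPM in 11-week MitoPark mice and 2.83 ± 1.00 CPM in floxed controls.

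Cholesterol synthesis genes fell in the same astrocyte-like nuclei. Of 24 members 4 fell, 0 rose and 20 did not pass (9 fell adjusted over the list alone, median -0.55, camera adjusted p = 8.17e-08, adjusted p = 0.201 with an estimated correlation). The synthase Hmgcs1 fell from 138 ± 19.7 to 40.2 ± 11.7 CPM (-1.68 ± 0.24, adjusted p = 4.53e-05), and also against each floxed pair (-1.72, adjusted p = 0.000704 and -1.64, adjusted p = 0.000278). Mvd (-2.04 ± 0.47) and Idi1 (-1.99 ± 0.46) fell, as did the matrix gene Tnc (-1.74 ± 0.34), the glutamate receptor Grm3 (-0.62 ± 0.13) and the water channel Aqp4 (-0.60 ± 0.16). The phagocytic receptor Mertk (0.87 ± 0.16) and the clock genes Per1 (1.32 ± 0.30), Per2 (1.08 ± 0.23) and Npas2 (0.69 ± 0.15) rose, and Gfap was at 18.2 ± 11.8 against 19.9 ± 9.08 CPM (adjusted p = 0.978). In all 204 of 8865 genes changed (134 rose, 70 fell, 1143 at an unadjusted p under 0.05, 168 by DESeq2). Against floxed controls 4 and 6 there were 76 and against 5 and 7 238, and the count was 108 without floxed control 5, 39 without MitoPark replicate 2 and 122 against all 7 controls. Of 28 genes chosen by rule that passed in this class, 5 passed against controls 4 and 6, 23 against 5 and 7 and 4 against both (Fkbp5, Hmgcs1, Htra1 and Tnc), and 4 of the 28 passed in all 7 fits with 1 library left out.

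Oligodendrocyte-like nuclei of 11-week MitoPark mice changed in 907 of 13327 genes (501 rose, 406 fell, 2579 at an unadjusted p under 0.05, 967 by DESeq2). Of 40 myelin and lipid genes 2 rose and 12 fell (4 and 16 adjusted over the list alone, camera adjusted p = 0.000475, adjusted p = 0.802 with an estimated correlation), with Adamts4 (-0.97 ± 0.14), Gal3st1 (-0.65 ± 0.11) and Car2 (-0.55 ± 0.11) lower and Kcna1 higher (0.95 ± 0.11). Of 19 clock genes 7 rose and 1 fell (9 and 1 adjusted over the list alone, camera adjusted p = 0.00474, adjusted p = 0.238 with an estimated correlation), Per2 by 2.54 ± 0.46, Cry1 by 1.04 ± 0.25 and Tef by 0.77 ± 0.14. Cholesterol synthesis genes fell in 3 of 26 (4 adjusted over the list alone, camera adjusted p = 1.22e-05, adjusted p = 0.518 with an estimated correlation), among them Dhcr7 (-1.05 ± 0.25). Ddc (1.24 ± 0.19), Kcnab1 (1.16 ± 0.16) and Nrxn2 (0.96 ± 0.11) rose, the ephrin receptor Ephb1 (-0.97 ± 0.13), Sema6a (-0.66 ± 0.13) and the lineage factor Nkx2-2 (-1.72 ± 0.26) fell, and C4b (-0.11 ± 0.29, adjusted p = 0.906) and Mbp (-0.05 ± 0.12, adjusted p = 0.894) did not pass. Cluster 12 held 44.8% ± 11.2 of the class at 11 weeks and 0.28% ± 0.46 in floxed controls, while cluster 1 held 6.41% ± 4.71 against 38.6% ± 10.1 (SD, n = 3 and 4). The count was 219 against floxed controls 4 and 6 and 1014 against 5 and 7. Of 56 genes chosen by rule that passed, 14 and 47 did so against these pairs and 12 against both, among them Adamts4, Gal3st1, Kcna1, Tef, Ddc, Kcnab1, Nrxn2, Ephb1 and Nkx2-2 of those above, and 24 in all 7 fits with 1 library left out. The count was 581 and 521 without floxed control 7 or 5, 324 without MitoPark replicate 2 and 602 with only these 2 groups fitted.

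Microglia-like nuclei changed in 43 of 10140 genes at 11 weeks (39 rose, 4 fell, 987 at an unadjusted p under 0.05, 60 by DESeq2), with the clock gene Nr1d2 (0.95 ± 0.22) and Per1 (2.24 ± 0.51) higher and Nrp1 (-0.77 ± 0.16) and the mechanosensitive channel Piezo1 (-1.21 ± 0.28) lower. P2ry12 (-0.25 ± 0.14, adjusted p = 0.587) and Apoe (0.26 ± 0.71, adjusted p = 0.974) did not pass. The count was 5 against floxed controls 4 and 6 and 30 against 5 and 7. Of 9 genes chosen by rule that passed, 0 passed against 4 and 6, 4 against 5 and 7 and 0 in all 7 fits with 1 library left out. The count was 19, 3 and 20 without floxed control 6, 7 or 5, 3 and 21 without MitoPark replicate 2 or 3, 1 with doublets kept and 152 with no filter. Oligodendrocyte precursor-like nuclei changed in 50 of 9414 genes (45 rose, 5 fell), and Tnc fell by 2.89 ± 0.48 on the log2 scale. Sst/Npy interneuron-like nuclei changed in 18 of 7345 genes (13 rose, 5 fell). These classes together had 68 genes, and 40, 37 and 124 without floxed control 6, 7 or 5 and 249 and 25 without MitoPark replicate 1 or 2. There the cortical marker Slc17a7 was at 48.3 ± 5.6 against 9.18 ± 3.67 CPM and the oligodendrocyte marker Mobp at 43.6 ± 22.4 against 8.07 ± 9.97 CPM.

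In D1 SPN-like nuclei of 11-week MitoPark mice the mitochondrial folate enzyme Mthfd1l rose from 16.9 ± 2.70 to 34.7 ± 4.57 CPM (1.01 ± 0.17), the ubiquitin protease Usp3 from 137 ± 8.35 to 238 ± 39.6 CPM (0.80 ± 0.12), and the sorting nexin Snx24 (0.74 ± 0.11), the synaptic adhesion gene Lrrtm4 (0.55 ± 0.092), the active zone gene Erc2 (0.40 ± 0.076) and the calcium channel subunit Cacnb2 (0.55 ± 0.11) rose. The actin-binding gene Nexn fell (-0.73 ± 0.12). Mthfd1l, Usp3, Snx24, Nexn and Lrrtm4 passed against each floxed pair and in all 7 fits with 1 library left out. Clock genes rose as a list, 1 of 19 passing (Ciart, 1.48 ± 0.25) and 6 adjusted over the list alone (camera adjusted p = 8.84e-06, adjusted p = 0.293 with an estimated correlation). Activity-regulated genes were lower with 0 of 29 passing (1 adjusted over the list alone, median -0.76, camera adjusted p = 4.1e-05, adjusted p = 0.785 with an estimated correlation). Drd1 (-0.18 ± 0.11, adjusted p = 0.58), Tac1 (0.38 ± 0.16, adjusted p = 0.42) and Tfam (-0.25 ± 0.22, adjusted p = 0.721) did not pass.

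In D2 SPN-like nuclei Snx24 (0.97 ± 0.13), Grb14 (1.28 ± 0.25), Nrip1 (0.91 ± 0.18), Kcnip3 (0.70 ± 0.14) and Erc2 (0.49 ± 0.082) rose, while Adora2a (-0.38 ± 0.097, adjusted p = 0.112) and Drd2 (0.10 ± 0.090, adjusted p = 0.764) did not pass. Of 7 genes chosen by rule that passed in D2, only Snx24 passed against floxed controls 4 and 6, 5 passed against 5 and 7, and 0 passed in all 7 fits with 1 library left out. The count was 40 of 12983 in D1 (37 rose, 3 fell, 1389 at an unadjusted p under 0.05, 121 by DESeq2) and 23 of 12635 in D2 (all rose, 1332 and 82). Against floxed controls 4 and 6 these were 45 and 12, and against 5 and 7 293 and 172. The D1 count was 122 without floxed control 4 and 23, 17 and 22 without MitoPark replicate 1, 2 or 3, and 294 with no filter. The D2 count was 81, 7, 11 and 6 without floxed control 4, 6, 7 or 5, 0 and 8 without MitoPark replicate 2 or 3, 292 with no filter, 5 with only these 2 groups fitted, 13 against all 7 controls and 10 with each library clustered on its own. The MitoPark change differed between the SPN classes in 1 gene, Cntnap3 (adjusted p = 5.79e-07), which was chosen after its values were seen, and in 2 to 8 genes with any 1 of the 7 libraries left out. In the late group 0 genes differed by edgeR (668 at an unadjusted p under 0.05), 1 and 2 without floxed control 6 or 5, and 10 and 8 without 15-week replicate 1 or 4.

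Cytosolic ribosomal protein genes and nuclear-encoded oxidative phosphorylation genes were lower at 11 weeks in all 8 classes tested, neurons and glia alike. In D1 SPN-like nuclei the medians were -0.53 and -0.30 with 0 members passing (camera adjusted p = 6.58e-16 and 2.2e-08, adjusted p = 0.785 and 0.791 with an estimated correlation). Heat shock genes were lower in 4 classes at 11 weeks (lowest adjusted p 0.0106, and 0.812 there with an estimated correlation) and in 4 after 6-OHDA (0.00982 and 0.389). MitoPark 11-week replicate 3 had 23.1% of its nuclei called doublets and 33.8% in unnamed clusters, against 7.39% and 17.69% over all libraries.

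Late MitoPark mice were compared with the same floxed controls, again of unstated age. In D1 SPN-like nuclei 32 genes fell and 8 rose. The proteoglycan Vcan fell from 34.9 ± 9.62 to 14.3 ± 2.46 CPM (-1.26 ± 0.17, adjusted p = 0.00113), the vesicle gene Synpr from 274 ± 74.1 to 136 ± 24.5 CPM, Homer1 from 530 ± 102 to 354 ± 37.2 CPM (-0.58 ± 0.12), and Unc13a (-0.59 ± 0.12), Cntnap5b (-0.73 ± 0.12), the kainate receptor Grik2 (-0.40 ± 0.079), Nrxn3 (-0.37 ± 0.077) and Epha6 (-0.38 ± 0.072) fell (n = 4 and 4). The splicing gene Rnpc3 rose (0.54 ± 0.085). Tac1 was at 131 ± 20.1 against 82.9 ± 14.5 CPM (0.64 ± 0.15, adjusted p = 0.067), higher in 4 of 4 libraries, and Drd1 (-0.03 ± 0.097, adjusted p = 0.949) did not pass. Against floxed controls 4 and 6 all 11 named genes passed, and against 5 and 7 only Vcan did (-0.90, adjusted p = 0.03), with Homer1 at -0.34 (adjusted p = 0.377) and Unc13a at -0.31 (adjusted p = 0.379). Of these 11 genes, 2 passed in all 8 fits with 1 library left out.

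Several lists of synaptic genes were lower in late D1 SPN-like nuclei with few members passing. Postsynaptic scaffold genes had 1 of 36 fall (8 adjusted over the list alone, camera adjusted p = 3.22e-07, adjusted p = 0.173 with an estimated correlation), calcium and sodium channels 0 of 30 (10 adjusted over the list alone, camera adjusted p = 3.22e-07, adjusted p = 0.266 with an estimated correlation), and axon guidance genes 1 of 39 (1 up and 10 down adjusted over the list alone, camera adjusted p = 2.24e-06, adjusted p = 0.173 with an estimated correlation). Glutamate receptors had 1 of 34 fall (1 up and 8 down adjusted over the list alone, camera adjusted p = 1.26e-05, adjusted p = 0.173 with an estimated correlation) and presynaptic genes 2 of 40 (3 adjusted over the list alone, camera adjusted p = 0.00246, adjusted p = 0.266 with an estimated correlation). Postsynaptic, calcium channel and glutamate receptor genes were lower against each floxed pair in D1, weakly against 5 and 7 (adjusted p = 0.0186 for each). In D2 SPN-like nuclei axon guidance genes were lower with 0 of 39 passing (also 0 adjusted over the list alone, camera adjusted p = 4.86e-07, adjusted p = 0.0534 with an estimated correlation), and called against each floxed pair. Glutamate receptor, postsynaptic and calcium channel genes were lower there too (adjusted p = 0.246, 0.253 and 0.34 with an estimated correlation), the last 2 not against controls 5 and 7 (adjusted p = 0.078 and 0.379).

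The counts against floxed controls were 40 of 12983 genes in D1 (8 rose, 32 fell, 1953 at an unadjusted p under 0.05, 353 by DESeq2) and 1 of 12635 in D2 (1392 and 90). Against floxed controls 4 and 6 they were 1283 and 779, and against 5 and 7 they were 5 and 2. The D1 count was 8, 7 and 477 without floxed control 4, 6 or 7, 19 without MitoPark 15-week replicate 1, and 5 and 7 without 18-week replicate 1 or 2. It was 2 and 15 with the 15-week or 18-week libraries alone, 9 with only these 2 groups fitted, 339 against all 7 controls, 17 with each library clustered on its own, 12 with depth and 5 with Xist as a covariate, and 522 with no filter. The D2 count was 0, 135 and 0 without floxed control 6, 7 or 5, 2 and 7 without 15-week replicate 1 or 4, 0 without 18-week replicate 1 or 2, 315 with no filter and 9 against all 7 controls.

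Late glia changed in few genes. In astrocyte-like nuclei the sulfotransferase gene Hs3st3a1 rose (1.34 ± 0.24) and Grm3 fell (-0.61 ± 0.12), 2 of the 4 changes among 8865 genes (814 at an unadjusted p under 0.05, 34 by DESeq2), and 97 and 0 passed against floxed controls 4 and 6 and 5 and 7. That count was 8 and 34 without floxed control 6 or 7, 0 with doublets kept and 0 with the 15-week or 18-week libraries alone. In oligodendrocyte-like nuclei 0 of 13327 passed by edgeR (1642 at an unadjusted p under 0.05, 301 by DESeq2, 255 and 0 against the pairs, 15 without floxed control 7, 1 without 15-week replicate 4 or 18-week replicate 2), and in microglia-like nuclei 0 of 10140 (714, 12, 14 and 0, and 1 without 15-week replicate 4). Fkbp5 in oligodendrocyte-like nuclei reached 103 CPM in 15-week replicate 4, against 16.4 to 30.8 in the other 3 late libraries. Clock genes were higher as a list in 4 classes, with 0 of 15 passing in microglia-like nuclei (6 up and 1 down adjusted over the list alone, camera adjusted p = 5.1e-06, adjusted p = 0.0555 with an estimated correlation).

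Mitochondrially encoded mRNAs, which reach nuclei as carry-over from cytoplasm, were lower in 7 of 8 classes of late MitoPark mice, with a median of -1.98 in microglia-like nuclei (0 of 11 passing, 11 adjusted over the list alone, camera adjusted p = 1.28e-19, adjusted p = 0.101 with an estimated correlation). Median mitochondrial shares per nucleus were 0.138% in floxed control 6 and 0.008%, 0.0% and 0.017% in floxed controls 4, 5 and 7. In late libraries they were 0.0% to 0.006%. The list's fall may therefore rest in part on floxed control 6. Myelin genes were higher in 7 of 8 classes, neurons included (lowest adjusted p 5.45e-07, in microglia-like nuclei, and 0.468 there with an estimated correlation). The oligodendrocyte marker Mbp did not follow in D1 SPN-like nuclei, at 68.5 ± 3.08 CPM in late MitoPark mice against 66.7 ± 19.1 in floxed controls.

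Late and 11-week MitoPark mice were compared to follow the model over time. By camera, lists of synaptic genes were lower and ribosomal and oxidative phosphorylation genes higher in the late group in D1 and D2 SPN-like nuclei, but no list call there held with an estimated correlation (lowest adjusted p 0.224, in D1). In D1 SPN-like nuclei Lrrtm4 (-0.60 ± 0.092), Erc2 (-0.48 ± 0.075), Cacnb2 (-0.55 ± 0.11), Cacna1e (-0.46 ± 0.077), Nrxn3 (-0.44 ± 0.083), Grik2 (-0.44 ± 0.084), the GABA receptor Gabrg3 (-0.43 ± 0.079), Kcnh5 (-0.62 ± 0.12), Robo2 (-0.47 ± 0.083), Egfem1 (-0.81 ± 0.12) and Grb14 (-1.36 ± 0.34) fell, and Cox7c (0.73 ± 0.18) and Pnmal2 (0.95 ± 0.19) rose. Of 30 calcium and sodium channels 8 fell and 1 rose (16 and 1 adjusted over the list alone, camera adjusted p = 2.36e-06, adjusted p = 0.353 with an estimated correlation), and of 36 postsynaptic genes 9 fell (1 up and 15 down adjusted over the list alone, camera adjusted p = 2.38e-05, adjusted p = 0.224 with an estimated correlation). In D2 SPN-like nuclei Erc2 (-0.52 ± 0.082), Mpp7 (-0.70 ± 0.11) and Kcnh5 (-0.58 ± 0.098) fell and Syngr3 (1.08 ± 0.17) and Adora2a (0.38 ± 0.097) rose. Ribosomal protein genes were higher in all 8 classes (lowest adjusted p 5.43e-16, in cortical glutamatergic neuron-like nuclei, and 0.553 there with an estimated correlation).

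The D1 count was 651 of 12983 (166 rose, 485 fell) and the D2 count 203 of 12635 (52 rose, 151 fell). Without MitoPark 11-week replicate 1, 2 or 3 these were 273, 99 and 4 in D1 and 82, 0 and 4 in D2. Without 15-week replicate 1 and 18-week replicate 1 or 2 they were 421, 134 and 59 in D1 and 81, 14 and 2 in D2. With depth as a covariate they were 185 and 71, with Xist as a covariate 303 and 12, with each library clustered on its own 220 and 0, and with no filter 1013 and 656. DESeq2 called 928 and 672, and 2756 and 2400 had an unadjusted p under 0.05. Only Lrrtm4 and Erc2 of 51 named D1 genes passed in all 7 such fits, and none of 26 named D2 genes did.

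Floxed and untreated C57BL/6J controls were compared to see what separates the controls themselves. Bicc1, an RNA-binding protein gene next to Tfam on chromosome 10 (70922832 to 71159700, with Tfam at 71225464 to 71238280), rose from 37.1 ± 2.32 to 274 ± 121 CPM in D1 SPN-like nuclei (2.88 ± 0.31, adjusted p = 0.00223) and from 31.1 ± 7.95 to 244 ± 99.7 CPM in D2 (3.06 ± 0.32). Floxed controls 4 and 6 were at 364 and 392 CPM and controls 7 and 5 at 171 and 167 CPM in D1. Tfam itself was at 13.6 ± 0.96 against 6.84 ± 3.02 CPM in D1 (0.87 ± 0.25, adjusted p = 0.145), and it did not pass in either MitoPark group against floxed controls. Cre acts in dopamine neurons, whose nuclei lie outside the striatum. The cell cycle gene Ccnd2 fell in D2 (-0.98 ± 0.16). The counts were 5 of 12983 genes in D1 (1608 at an unadjusted p under 0.05, 78 by DESeq2) and 22 of 12635 in D2 (1468 and 39). Without floxed control 4 they were 157 and 114, and without C57BL/6J replicate 1, 2 or 3 the D2 count was 10, 4 and 14. The D1 count without C57BL/6J replicate 2 or 3 was 2 and 9, and without floxed control 7 or 5 it was 10 and 11. The D2 count without floxed control 6, 7 or 5 was 4, 7 and 7. Ribosomal protein genes were higher in the floxed controls in D1 with 0 of 77 passing, also adjusted over the list alone (camera adjusted p = 6.45e-19, adjusted p = 0.881 with an estimated correlation).

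**Figure D4:**
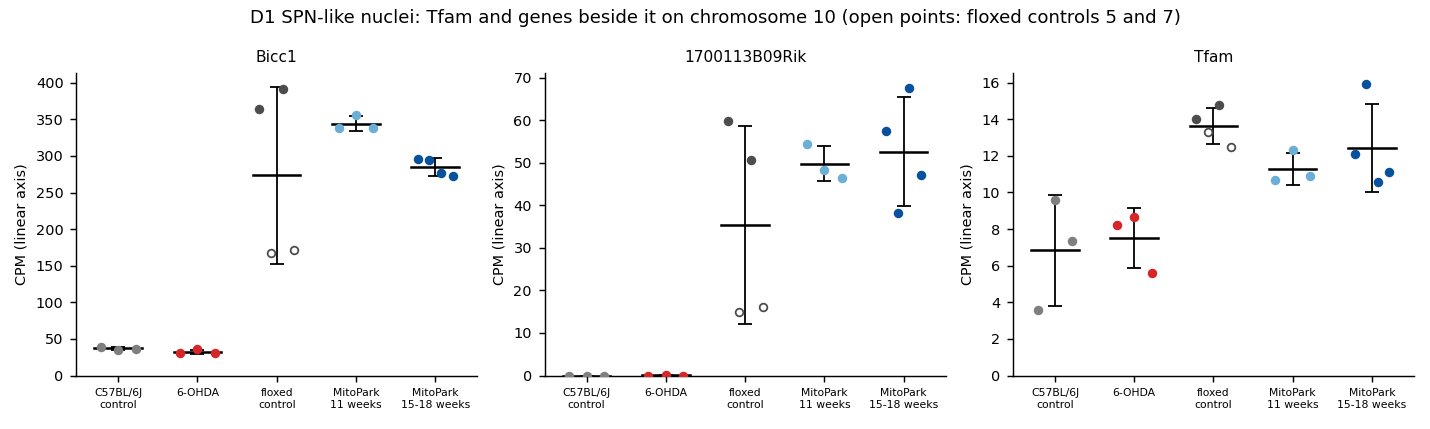
Expression (CPM) of Bicc1, 1700113B09Rik and Tfam in D1 SPN-like nuclei of C57BL/6J controls, 6-OHDA, floxed controls, 11-week MitoPark and late MitoPark. Points are libraries (open for floxed controls 5 and 7), bars are means and whiskers SD; Bicc1 is at 37.1 ± 2.32 CPM in C57BL/6J controls, at 171 and 167 CPM in floxed controls 7 and 5 and at 364 and 392 CPM in floxed controls 4 and 6.

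The toxin and the genetic model were set side by side with no library in common. Across 6685 genes of D1 SPN-like nuclei, the 6-OHDA and late MitoPark changes had a Pearson r of 0.24 and a Spearman rho of 0.22 (genes are not independent replicates). Of the 480 genes changed by 6-OHDA, 357 had the same sign in late MitoPark mice, and 14 passed in both in the same direction, 1 up and 13 down, where independent calls would give 0.126 and 0.678. Homer1, Unc13a and Nrxn3 fell in both. This overlap rests on all 4 floxed controls as 1 group, since against controls 5 and 7 alone none of these 3 genes passed late (adjusted p = 0.377, 0.379 and 0.356). The change itself differed between the models in 63 genes of D1 SPN-like nuclei (33 higher and 30 lower after 6-OHDA) and in 5 of D2. In D2 SPN-like nuclei 29 of 49 genes had the same sign in late MitoPark mice (r = -0.005). In oligodendrocyte-like nuclei 82 of the 94 genes changed by 6-OHDA had the same sign in late MitoPark mice, and 18 rose and 12 fell in both 6-OHDA and 11-week MitoPark mice, against 1.69 and 1.49 for independent calls. The 11-week and late MitoPark changes share their floxed controls, which alone give a correlation. Their r in D1 was 0.29, against 0.47 in simulations with shared controls and no effect, and with the controls split it ran from -0.35 to 0.13.

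The other classes and lists are summed up here. Oligodendrocyte precursor-like nuclei changed in 6 genes after 6-OHDA (the ephrin receptor Ephb1 fell by 1.20 ± 0.25) and in 8 in late MitoPark mice. With the Sst/Npy interneuron-like nuclei these were 7 and 8, and 2 without 6-OHDA replicate 2. The late 8 became 14, 2 and 1 without floxed control 4, 6 or 5, 1 and 20 without 15-week replicate 1 or 4 and 0 without 18-week replicate 1. Cortical glutamatergic neuron-like nuclei changed in 3 genes after 6-OHDA, in 0 at 11 weeks by edgeR (971 at an unadjusted p under 0.05, 20 by DESeq2) and in 10 in the late group, Trf among them (1.52 ± 0.25). Cck/Vip interneuron-like nuclei changed in 1, 0 and 0 genes, Sst/Npy interneuron-like nuclei in 1 after 6-OHDA and 0 in the late group, and eccentric SPN-like nuclei in 0 in both MitoPark groups by edgeR. Dopaminergic terminal transcripts were called in no class (lowest adjusted p 0.156), Tfam and mitochondrial biogenesis genes only for floxed against C57BL/6J controls (2 classes, lowest adjusted p 0.0203), and potassium channels only in late cortical glutamatergic neuron-like nuclei (adjusted p = 0.0215). Dopamine receptor signalling genes were lower in 4 classes in the late group (lowest adjusted p 0.00204), neuropeptide genes were higher in 3 (0.00148) and presynaptic genes lower in 2 (0.000893). Disease-associated microglia and oligodendrocyte genes were higher in 4 and 3 classes in the late group (0.000159 and 0.00111). Homeostatic microglia genes were higher in 2 classes in the late group (0.0021), homeostatic astrocyte genes in 1 class at 11 weeks (0.0108), and stress and p53 genes in 1 class after 6-OHDA (0.00872). GABA receptor genes were higher in 1 class at 11 weeks (0.00634) and lower in 1 in the late group (0.0423). None of these calls held with an estimated correlation. The sign of the median, the mean and the test differed in 154 of the 879 list tests, 0 of them called.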

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

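The tests of explanations in this part (other controls, depth, free RNA, other libraries, single libraries) and the comparison of ages in glia were chosen after the results were seen. The tests of differences between D1 and D2 SPN-like nuclei, between ages in SPNs and between the models were planned.

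The response to 6-OHDA differed between D1 and D2 SPN-like nuclei in 798 genes by a test of the difference itself. As D2 minus D1 on the log2 scale, the difference was above 0 for Nr4a1 (3.70), Mir670hg (3.62), Fos (3.59), Vgf (3.03), Ryr1 (2.11), Kcnn2 (1.35), Ntng1 (1.31), Unc13a (0.93), Homer1 (0.77), Tac1 (0.76), Gad1 (0.62), Gabra5 (0.59), Gad2 (0.58), Kcnq3 (0.53), Dlgap3 (0.52), Srebf2 (0.46) and Pde1b (0.43). It was below 0 for Slit1 (-1.74), Fa2h (-1.71), Hrh3 (-1.52), Gpr149 (-1.32), Abca1 (-1.24), Per3 (-0.91) and Sv2c (-0.38). At 11 weeks of MitoPark 1 gene differed, Cntnap3 (1.44).

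In D1 SPN-like nuclei the 480 genes of the 6-OHDA response were weighed against 3 technical explanations. If the C57BL/6J controls alone stood apart, 6-OHDA libraries would not differ from the floxed controls. Genes were therefore called without 1 6-OHDA library and measured in that library, where no difference gives a median near 0. In the genes' direction the 3 libraries lay 0.532, 0.525 and 0.537 above the floxed controls (0.729, 0.735 and 0.769 above C57BL/6J), and 302 of the 480 genes also passed against floxed controls. A shift of the whole library would move D2 alike, but 798 of all tested genes differed between the classes (highest other split 19). With depth as a covariate the median was 0.768, and 388 of the 480 were among the 425 genes called. A response of D1 SPNs to dopamine loss stays a hypothesis, with the injection (no sham animals), hemisphere and unrecorded sets of libraries untested.

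The 2 ages of MitoPark mice differed directly in 651 genes of D1 and 203 of D2 SPN-like nuclei. In D1 the late minus 11-week value was -1.36 for Grb14, -0.81 for Synpr and Egfem1, -0.62 for Kcnh5, -0.60 for Lrrtm4, -0.55 for Cacnb2, Snx24 and Usp3, -0.51 for Homer1, -0.48 for Erc2, -0.47 for Robo2, -0.46 for Cacna1e, -0.44 for Nrxn3 and Grik2, -0.43 for Gabrg3 and -0.33 for Epha6. It was 0.32 for Rnpc3, 0.73 for Cox7c and 0.95 for Pnmal2. In D2 it was -1.29 for Grb14, -0.70 for Mpp7, -0.64 for Snx24, -0.58 for Kcnh5, -0.52 for Erc2, 0.38 for Adora2a and 1.08 for Syngr3.

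For D1 this pattern may in part be a difference between sets of libraries. Floxed controls 5 and 7 differed from 4 and 6 by a median of 0.218 in the direction of these genes (0.418 for age), with the same sign in 599 of 651. Depth per nucleus as the whole cause was excluded, with a median of 0.467 with the covariate, although the count fell to 185. Without MitoPark 11-week replicate 3 the median was 0.391. That library helped call these genes, so this median could not exclude it as the cause. The count fell to 4 without it (273 and 99 without replicate 1 or 2), and why was not tested. Age, sex (fewer genes with Xist as a covariate) and unrecorded sets of libraries therefore stay open.

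In glia the same test of age differed in 951 genes of oligodendrocyte-like, 99 of astrocyte-like, 24 of microglia-like and 61 of oligodendrocyte precursor-like nuclei. Late minus 11-week values in oligodendrocyte-like nuclei were -4.29 for Cdkn1a, -2.54 for Fkbp5, -2.43 for Plin4, -1.66 for Pdk4, -0.80 for Nrxn2, -0.71 for Ddc, -0.54 for Kcna1, 0.46 for Gal3st1, 0.56 for Ephb1, 0.66 for Adamts4 and Car2 and 1.46 for Nkx2-2. The clusters of this class shifted as well, with 44.8% at 11 weeks and 0.93% late in cluster 12 and 6.41% and 33.3% in cluster 1. They were -3.85, -0.99 and -0.77 for Fkbp5, Npas2 and Mertk in astrocyte-like nuclei, -2.60 for Zbtb16 in microglia-like nuclei, and -1.68, -1.16 and 2.33 for Fkbp5, Klf9 and Tnc in precursor-like nuclei. Without 11-week replicates 1, 2 and 3, 15-week replicates 1 and 4 and 18-week replicates 1 and 2, in this order, the counts were 598, 165, 593, 677, 878, 508 and 506 in oligodendrocyte-like, 68, 17, 57, 61, 143, 38 and 33 in astrocyte-like, 48, 0, 6, 4, 59, 4 and 0 in microglia-like and 31, 3, 62, 18, 93, 22 and 6 in precursor-like nuclei.

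Between the models the change differed in 63 genes of D1 and 5 of D2 SPN-like nuclei. As 6-OHDA minus late MitoPark, the D1 difference was 2.02 for Slit1, 1.46 for Gpr149, 0.58 for Sv2c, -0.64 for Neto2 and -1.72 for Ryr1.

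In 12 cases a library lay far from the other 3 of its group by Dixon's test, among 226 groups of 4 tested, and chance alone gives about 1 in 20 groups. MitoPark 18-week replicate 2 was low in total UMIs (38404839) and nuclei used (5248). Floxed control 6 was high in its share of ependymal cell-like nuclei (1.56%), floxed control 7 was low in Kcna1 of oligodendrocyte-like nuclei (217 CPM), and 15-week replicate 1 was high in Gfap of astrocyte-like nuclei (37.5 CPM). Floxed control 4 was high in Kcnh5 of D1 SPN-like (113 CPM), Tsc22d3 of microglia-like (50.4 CPM) and Plin4 of oligodendrocyte-like nuclei (4.99 CPM). MitoPark 15-week replicate 4 was high in Fkbp5 (103 CPM) and Cdkn1a (2.72 CPM) and low in Nkx2-2 (27.3 CPM) of oligodendrocyte-like nuclei, and high in Klf9 of precursor-like nuclei (74 CPM).

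The glucocorticoid-responsive genes of glia, high in the 11-week mice, were also high in this library. The list was called in 5 classes at 11 weeks, in 4 in the late group (lowest adjusted p 5.42e-05, and 0.875 there with an estimated correlation) and in 3 after 6-OHDA, and all 3 6-OHDA libraries (0.817 to 1.22) scored above the highest control (0.486). Free RNA from another class would need a median of 51.4% of its transcripts, against 9.86% as the highest share of a marker, and with depth as a covariate the median change was 2.31 (2.25 without), so both were excluded as the whole cause. For 2 of the 26 calls, Fkbp5 of astrocyte-like (5.63%) and Zbtb16 of microglia-like nuclei (3.18%), the share needed was below 9.86%, so free RNA was not excluded for them. A passing state of the animals, such as stress or the hour of collection, that any library can show, remains open, since 2 of the 14 libraries outside the 11-week group reached its lowest score of 1.17 (the list's mean log2 CPM over the 3 glial classes, relative to the 7 controls), 15-week replicate 4 (1.20) and 6-OHDA replicate 3 (1.22). An effect of the MitoPark genotype at 11 weeks is equally open, and the hour of collection is not in the labels.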

How the results depend on the processing

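The floxed-control fits (floxed for C57BL/6J controls, or a floxed pair left out) were chosen after the results were seen, and other alternatives were planned. The counts below are of changed genes, in D1, D2, astrocyte-like, oligodendrocyte-like and microglia-like nuclei, and a value is given wherever it lay beyond 1.5 times the reported count. Unless a reason is named, the cause was not tested.

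The D1 response to 6-OHDA (480) was within 1.5 times of its count by DESeq2, RLE factors, doublets kept, stricter nuclei, depth, Xist, only these 2 groups and the replicate block. With RLE factors all 17 counts refitted lay within that range. Of the values of single genes chosen by rule under all alternatives, 4933 stayed on the same side of the threshold (in direction too where called), 1439 kept direction but no longer passed, 18 newly passed, 79 without a call moved by more than 1 SE, and 1 called value reversed. That was Itpr2 in oligodendrocyte-like nuclei at 11 weeks, at -0.60 with each library clustered on its own. No class share passed under any of its 5 alternatives.

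With 1 library left out, the counts for 6-OHDA ran from 227 to 357 in D1 (480), 1 to 56 in D2 (49), 1 to 6 in astrocyte-like (9), 25 to 122 in oligodendrocyte-like (94) and 0 to 2 in microglia-like nuclei (0). For 11-week MitoPark they ran from 17 to 122 (40), 0 to 81 (23), 39 to 229 (204), 324 to 963 (907) and 3 to 35 (43). For late MitoPark they ran from 5 to 477 (40), 0 to 135 (1), 3 to 34 (4), 0 to 15 (0) and 0 to 1 (0). Late against 11 weeks gave 4 to 566 in D1 (651) and 0 to 174 in D2 (203), and floxed against C57BL/6J 2 to 157 (5) and 4 to 114 (22). The precursor and Sst/Npy classes together gave 2 to 10 (7), 25 to 249 (68) and 0 to 20 (8) for the 3 comparisons. The difference between D1 and D2 responses ran from 460 to 869 (798), 2 to 8 (1) and 0 to 10 (0), and the lists called in D2 after 6-OHDA from 0 to 2 (0). Fewer libraries leave fewer degrees of freedom, and the cause of a rise when a floxed control is left out was not tested.

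With floxed controls 5 and 7 left out, late MitoPark gave 1210 genes in D1, 740 in D2, 103 in astrocyte-like, 197 in oligodendrocyte-like and 7 in microglia-like nuclei. The 11-week counts were then 14 in D2, 84, 221 and 7 in the glia. With 4 and 6 left out, D1 and D2 had 326 and 171 genes at 11 weeks and 7 and 7 late, and late astrocyte-like nuclei 0. In the report both pairs were in 1 fit, so its counts differ. With floxed in place of C57BL/6J controls the 6-OHDA counts were 1038 in D1 and 503 in D2.

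With no filter on low counts, 6-OHDA gave 814, 358, 40 and 50 genes in D1, D2, astrocyte-like and microglia-like nuclei. The 11-week counts were 294, 292 and 152 in D1, D2 and microglia-like, the late counts 522, 315, 37, 20 and 30 in the 5 classes, and late against 11 weeks 1013 and 656. DESeq2 gave 121 and 82 in D1 and D2 at 11 weeks, 353, 90, 34, 301 and 12 in the 5 classes late, 101, 27, 233 and 3 after 6-OHDA in D2, astrocyte-like, oligodendrocyte-like and microglia-like nuclei, 672 for late against 11 weeks in D2, and 19 and 3 in precursor and Sst/Npy classes after 6-OHDA and late.

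With all 7 controls as 1 group, 6-OHDA gave 880, 325, 61, 413 and 15 genes in the 5 classes, 11 weeks 13 and 122 in D2 and astrocyte-like, and late 339, 9 and 25 in D1, D2 and oligodendrocyte-like nuclei. With only the 2 groups compared, the counts were 89 and 15 after 6-OHDA in D2 and oligodendrocyte-like, 5 and 602 at 11 weeks in the same classes, 9, 3, 15 and 3 late in D1, D2, astrocyte-like and microglia-like nuclei, and 560 for late against 11 weeks in D2. The spread was then estimated from fewer libraries. The replicate block, with only those 2 groups, gave 88 in D2 and 24 in oligodendrocyte-like nuclei after 6-OHDA, and 2 lists in D2. Whether the numbers pair the animals stayed open.

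With each library clustered on its own, late MitoPark gave 17, 0, 8 and 1 genes in D1, D2, astrocyte-like and microglia-like nuclei, 11 weeks 10 in D2, 6-OHDA 2 and 55 in astrocyte-like and oligodendrocyte-like, and late against 11 weeks 220 in D1 and 0 in D2. That setting gave no value for D1 and D2 after 6-OHDA, where only 1 C57BL/6J library had clusters named as these classes, and fewer libraries had them in the other groups too. With doublets kept, astrocyte-like nuclei had 1 after 6-OHDA and 0 late, and microglia-like 1 at 11 weeks. With stricter nuclei the counts were 4 and 8 in astrocyte-like after 6-OHDA and late, and 1 in late oligodendrocyte-like and in microglia-like nuclei after 6-OHDA.

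With depth as a covariate, late MitoPark gave 12, 5 and 4 genes in D1, D2 and microglia-like nuclei, late against 11 weeks 185 and 71, and 6-OHDA 5 and 28 in astrocyte-like and oligodendrocyte-like nuclei. With Xist as a covariate, late gave 5, 0 and 8 in D1, D2 and astrocyte-like nuclei and late against 11 weeks 303 and 12. The 15-week libraries alone gave 2, 0 and 0 and the 18-week libraries alone 15 in D1 and 0 in astrocyte-like nuclei.

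For gene lists, the reported calls by camera were 5, 5 and 11 in D1 for the 3 comparisons, 0, 7 and 8 in D2 and 15, 17 and 22 in the 3 glial classes. With an estimated correlation each of these was 0. By fry they were 1, 0 and 5 in D1, and 0 and 1 in D2 at 11 weeks and late. Camera with a preset correlation therefore ranks lists against each other but does not allow for genes that move together from animal to animal.

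Why fewer simulated 2-fold changes were found in astrocyte-like nuclei after 6-OHDA (22.4%) than in D1 (88.1%) was not tested.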

Other observations

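The tests of hypotheses in this part, and the choice of single genes outside the named-gene rule, were made after the results were seen. Refitting other splits of the libraries was planned, with its reading set down after the results were seen.

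The genes that 6-OHDA changed in D1 SPN-like nuclei were scored in every library, as their mean log2 CPM in the direction of the response, relative to the mean of the 7 controls. MitoPark libraries lay between both ends, from 0.245 to 0.276 at 11 weeks, at 0.219 and 0.275 at 15 weeks and at 0.393 and 0.347 at 18 weeks, against 0.764 to 0.779 after 6-OHDA and -0.014, 0.101, 0.175 and 0.160 in floxed controls 4, 6, 7 and 5. Whether a part of the 6-OHDA response of D1 SPNs is present in MitoPark mice was tested. The 7 MitoPark libraries exceeded the 4 floxed controls by 0.181 (two-sided exact permutation p = 0.00303, higher than every floxed control in 7 of 7). At 11 weeks the difference was 0.152 (exact permutation p = 0.0571 over 35 splits) and late it was 0.203 (p = 0.0286, exact permutation), with 0.0571 as the highest of the 3 adjusted values. These tests take the 4 controls as alike, but controls 5 and 7 lay 0.124 above 4 and 6. The 7 libraries exceeded 4 and 6 by 0.243 and 5 and 7 by 0.119 (11 weeks 0.214 and 0.0898, late 0.265 and 0.141). The difference from the nearer pair was below that between the pairs for all 7 libraries and at 11 weeks and little above it late, so the hypothesis stays open.

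Around Tfam, a stretch of donor-strain DNA carried along with the floxed allele is a candidate explanation for the genes that separate the controls. Of 5 genes that differed between floxed and C57BL/6J controls in D1, 2 lay within 5 Mb of Tfam, where 42 of 12983 tested genes lie (Fisher's exact p = 0.000102), and in oligodendrocyte-like nuclei 3 of 6 (Fisher's exact p = 7.14e-07). Bicc1 was 3.36 (log2) above C57BL/6J in floxed controls 4 and 6 and 2.20 in 5 and 7 (adjusted p = 2.76e-08 between pairs). C730027H18Rik, the other D1 gene, was 9.065 and 8.293 above (adjusted p = 0.145). The noncoding RNA 1700113B09Rik, not called in D1, was at 0 CPM in the C57BL/6J controls. It was at 59.9 and 50.7 CPM in controls 4 and 6 and at 16.1 and 14.9 CPM in 7 and 5. The labels give all 4 as TfamloxP/TfamloxP, and the pair difference stays unexplained.

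Another single gene separated the C57BL/6J controls from every other library. AC149090.1 was at 119.5 to 183.2 CPM in their D1 SPN-like nuclei and at 741.1 to 1464 CPM in the other 14 libraries, those of 6-OHDA included, so these controls may differ from the lesioned mice in something besides the lesion. Sex does not account for it, since neither the C57BL/6J nor the 6-OHDA group had a library with Xist above 50 CPM. Whether it is strain or date was not tested. By Xist in oligodendrocyte-like nuclei (above 50 CPM), 0 of 3 C57BL/6J, 0 of 3 6-OHDA, 2 of 4 floxed, 1 of 3 11-week, 1 of 2 15-week and 2 of 2 18-week libraries were female, so sex is uneven between MitoPark groups.

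Other splits of the same libraries were refitted. Taken 1 by 1, chance was excluded, with 1 of 35 splits as large, for late against 11 weeks in D1 (651 genes, highest other split 122) and D2 (203, 33), and at 11 weeks for astrocyte-like (204, 86), oligodendrocyte-like (907, 465), microglia-like (43, 3) and precursor-like nuclei (50, 43). A share of 1 in 35 is the smallest possible, and adjusted over the 24 counts above 0 with 35 or more splits the lowest share was 0.111, so as a set they exclude nothing. Taken 1 by 1, it was not excluded at 11 weeks in D1 (40 genes, 2 of 35 splits as large, highest other 106) and D2 (23, 4 of 35, 84), nor late in D1 (40, 2 of 35, 50), D2 (1, 8 of 35, 74), astrocyte-like (4, 2 of 35, 8), precursor-like (8, 2 of 35, 31) and cortical neuron-like nuclei (10, 2 of 35, 259). It was not excluded for floxed against C57BL/6J in D1 (5, 9 of 35, 198) and D2 (22, 6 of 35, 120), for the D1 against D2 difference at 11 weeks (1, 20 of 35, 12), and for the difference between models in D1 (63, 5 of 100, 187) and D2 (5, 6 of 100, 40). A real count of 0 is reached by 35 of 35 splits whatever the data, so nothing is read from these splits. The highest other counts were then 2, 1 and 17 late in oligodendrocyte-like and microglia-like nuclei and for D1 against D2, 885 in cortical neuron-like nuclei at 11 weeks, and 127 and 37 in eccentric SPN-like and 25 and 2 in Cck/Vip interneuron-like nuclei at 11 weeks and late.

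Gene lists called by camera were as many in other splits at 11 weeks in D1 (5 lists, 28 of 35 splits, highest other 12), D2 (7, 16 of 35, 13) and glia (17, 17 of 35, 41), and late in D1 (11, 5 of 35, 17), D2 (8, 14 of 35, 14) and glia (22, 25 of 35, 47), so chance was not excluded for these counts. Several of the splits that called most genes kept floxed controls 5 and 7 together, or set control 4 with the MitoPark mice, which points to a structure of the samples. With 3 against 3 libraries the 10 splits are too few for a share under 0.05. The real and highest other counts after 6-OHDA were 480 and 0 in D1, 49 and 2 in D2, 9 and 0 in astrocyte-like, 94 and 0 in oligodendrocyte-like, 0 and 1 in microglia-like, 6 and 1 in precursor-like, 54 and 0 in eccentric SPN-like and 3 and 0 in cortical neuron-like nuclei, and 798 and 19 for D1 against D2. For lists they were 5 and 10 in D1, 0 and 9 in D2 and 15 and 39 in glia, and for Sst/Npy interneuron-like nuclei 18 and 94 genes at 11 weeks and 0 and 2 late.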
